A study of Homo sapiens with 12 samples.

How the data were processed

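RNA was sequenced from 12 libraries of Jurkat cells, a human T cell acute lymphoblastic leukaemia line, grown per the labels' protocols in RPMI with fetal calf serum. Doxycycline was present or absent, at 1 ug/uL as the labels give it. RNA was extracted with a Qiagen RNeasy kit and libraries were made with the NEBNext kit for single-cell or low-input RNA, per the labels' protocols. The submitters' processing notes name kallisto 0.46.0 and DESeq2 1.22.2, with no role given. The genome build and transcript set were not given in the sources used here. The authors deposited 2 tables of TPM, a length-normalized abundance scaled to the same total in each library, per gene symbol. There was one with 55514 genes for 3 ZNF683 and 3 Mock libraries and one with 44389 genes for 3 Dox+ and 3 Dox- libraries. Each library summed to between 992730 and 998500 TPM over the genes listed, so a transcript that takes a large share of a library lowers every other value in it. TPM keeps no record of read number, so the depth of each library is unknown and no counting interval was computed.

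Groups were taken from the sample titles and genotype labels. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Among genes in both tables, no gene above 0 in either of 2 libraries had exactly equal values in them. The highest correlation of log2(TPM + 1) between any 2 libraries was 0.995. Because the 2 tables hold different gene sets and were deposited apart, each comparison was fitted within its own table.

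Genes with a mean of at least 1 TPM over the 6 libraries of a table were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment, with a threshold of 0.05. No count model was run, since TPM values are not counts. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes, and log2 changes are given ± their standard error. In the doxycycline table limma estimated an unlimited prior degrees of freedom, so the spread used for a gene was that of genes of its mean level and the gene's own spread hardly entered its test. A gene with overlapping groups can pass there through 1 extreme library. The difference between the 2 effects was fitted as a contrast over all 12 libraries, each effect taken within its own table. A total of 35 gene lists with 810 genes, all of which were found in the tables, was tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry, which tests whether a list's genes move at all and does not compare them with other genes. A list's shift is the mean log2 change of its members minus that of the other genes. Camera compares the genes' moderated test statistics rather than these shifts, so a shift and its test can differ in sign. With 3 libraries per group the smallest two-sided exact permutation p is 0.1, so that test cannot reach 0.05 here.

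Named genes followed a rule set before the data were examined. ZNF683 came first. Then came up to 10 of the largest rises and of the largest falls per comparison among genes past the threshold, with groups that did not overlap, a mean of at least 5 TPM in the higher group and a standard symbol; up to 8 genes past the threshold in both comparisons in the same direction and up to 4 in opposite directions; up to 3 members of each list with the smallest adjusted p; and a fixed panel of T cell genes. Genes named outside this rule are said to have been chosen after their values were seen. Gene positions and types are from GENCODE v29 on GRCh38, matched by symbol; 50672 and 40610 symbols of the 2 tables matched 1 gene each. Reads from near-identical copies, short RNAs inside longer transcripts and antisense partners cannot be told apart in gene-level TPM, and values of such genes are uncertain.

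The procedure was tested on simulated data with the spread of the real genes. For ZNF683 against Mock, 84% of genes changed by a log2 of 1 and 97% of those changed by 2 were called, with 15 of 16017 unchanged genes called. For Dox+ against Dox-, 0% and 36% were called, with 1 of 14515 unchanged genes called. The genes changed by 1 or 2 were drawn outside the gene lists and from a higher expression level than the filter required. The shares called therefore do not cover the lower genes tested. A list raised by a log2 of 0.5 was recovered in both simulations and no other list was called, not counting S phase and apoptosis regulator genes, which share members with it. The simulated noise was independent between genes and held no outlying library, so these rates do not bound false calls in the real libraries. Other splits of the real libraries called up to 14 lists for ZNF683 against Mock, and up to 12 lists and 106 genes for doxycycline. The alternatives were other pseudocounts (0.1 and 5), other filters, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, other limma settings, the replicate number as a block and leaving out each library in turn. Added after seeing the data were protein-coding genes only (with and without median-of-ratios scaling), rescaling without the transcript AL135790.1, and leaving out Dox- libraries 1 and 2 together. The values of 2 list members are not reported here, though both stayed in the list tests and counts.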

Results

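Gene expression was measured by RNA sequencing in 12 Jurkat libraries, in 2 comparisons of 3 libraries against 3. Jurkat is a human leukaemic T cell line. The labels set Jurkat cells with ZNF683 expression beside cells without it. The first comparison set libraries labelled as carrying doxycycline-induced ZNF683 against Mock libraries. The labels do not say whether the Mock cells received doxycycline, so that comparison may also hold a doxycycline difference. The second set a line titled with the same factor grown with doxycycline (Dox+) against the line without it (Dox-). ZNF683 encodes Hobit, a zinc finger transcription factor known from tissue-resident and effector lymphocytes. Values are TPM, with mean ± SD and n = 3 libraries per group unless stated, and depth is unknown.

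ZNF683 itself (chromosome 1, 26361634 to 26374522) was low in all 12 libraries and its groups did not separate clearly. It stood at 1.17, 1.76 and 1.04 TPM in the libraries labelled ZNF683 and at 0.715, 1.59 and 0.681 TPM in the Mock libraries (two-sided exact permutation p = 0.5; log2 change 0.24 ± 0.21, limma adjusted p = 0.611). In the doxycycline table it stood at 0.453, 0.774 and 0.571 TPM with doxycycline and at 0.115, 0.239 and 0.451 TPM without. Those groups did not overlap, though the lowest Dox+ library, at 0.453 TPM, was next to the highest Dox- library, at 0.451 TPM, and the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow. The gene was under the mean of 1 TPM needed for the limma test there. The ZNF683 transcript therefore does not check the group labels, and every direction below is between libraries as labelled.

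**Figure D1:**
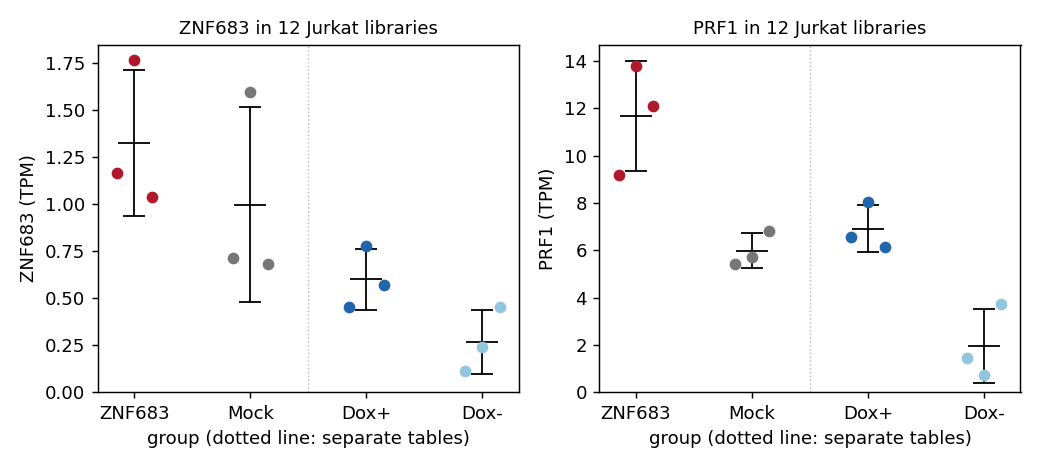
TPM of ZNF683 (left) and PRF1 (right) per library in the 4 groups; points are libraries, and the black bar and whiskers give the mean and SD of 3 libraries. ZNF683 stayed at or under 1.76 TPM in every library, while PRF1 had means of 11.7 against 5.99 TPM in the first table and 6.91 against 1.96 TPM in the second.

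Between the libraries labelled ZNF683 and Mock, 5 of 16588 tested genes passed the threshold, 3 higher and 2 lower, and 2152 had an unadjusted p under 0.05. HSPA6, a stress-inducible HSP70 chaperone gene (chromosome 1, 161524540 to 161526910), fell from 5.60 ± 1.41 to 0.511 ± 0.109 TPM (log2 change -2.11 ± 0.18, limma adjusted p = 0.0105). The other 4 were chosen after their values were seen, and each was listed at 0 in all 3 libraries of a group. The microRNA gene MIR128-1 was listed at 0 in the ZNF683 libraries and had 1.94, 2.63 and 2.08 TPM in the Mock libraries. AL132655.6 (6.67, 4.35 and 9.84 TPM), the microRNA gene MIR6816 (4.71, 2.64 and 4.36 TPM) and the antisense RNA AC017083.2 (2.23, 2.59 and 1.94 TPM) were present in the ZNF683 libraries and listed at 0 in the Mock libraries. Of the 4 called genes with a known length, the 2 microRNA genes were under 200 nt, against 3.65% of the genes tested, and values of such short genes are uncertain. The limma count was 0 without Mock library 2 (1117 genes at an unadjusted p under 0.05), 1 without Mock library 1, 3 without ZNF683 library 2, 8 without Mock library 3 and 49 without ZNF683 library 1. HSPA6 missed the threshold without ZNF683 library 2 or 3 or Mock library 1 or 2, at limma adjusted p from 0.0540 to 0.122, with log2 changes from -2.16 to -1.97.

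Of the 30 gene lists tested in this comparison, 5 passed at the preset correlation and none with an estimated correlation (adjusted p = 0.991 with an estimated correlation for each) or by fry's directional test. Cytosolic ribosomal protein genes were lower as a set (shift -0.38, camera adjusted p = 3.44e-12), with 41 of 42 members negative. None of the 42 passed singly: RPS29 had 632 ± 130 against 1076 ± 143 TPM, and RPS12 had 368 ± 102 against 577 ± 37.8 TPM. The list mean of ZNF683 library 3, at -0.02 against the Mock mean with median-of-ratios scaling, lay within the Mock libraries, unlike the -0.50 and -0.71 of the other ZNF683 libraries. Ribosome biogenesis and MYC target genes were higher as a set (shift 0.37, camera adjusted p = 3.11e-06; 28 of 29 positive), with ODC1, which encodes the polyamine-forming enzyme ornithine decarboxylase, at 35.8 ± 7.38 against 21.6 ± 6.39 TPM. Unfolded protein response genes (shift 0.25, camera adjusted p = 0.00167; 17 of 19 positive) included XBP1, a transcription factor of that response, at 160 ± 41.3 against 103 ± 8.85 TPM. Genes of the T cell receptor complex and its proximal signalling (shift 0.17, camera adjusted p = 0.00178; 22 of 27 positive) included the receptor-associated adaptor gene TRAT1, at 112 ± 15.9 against 65.3 ± 16.8 TPM, and the CD45 gene PTPRC, at 306 ± 23.6 against 229 ± 30.4 TPM. S phase genes had a shift of 0.12 (camera adjusted p = 0.00432; 37 of 42 positive), which did not pass without ZNF683 library 1 (shift 0.07, camera adjusted p = 0.152). HELLS, a chromatin remodeller of that list, had the opposite order at 68.2 ± 4.55 against 89.6 ± 6.98 TPM. With median-of-ratios scaling the library means of the 2 groups overlapped in 4 of these 5 lists, all but the T cell receptor list. Mock library 3 lay at 0.38 for ribosome biogenesis, above ZNF683 libraries 2 (0.34) and 3 (0.22), and above ZNF683 library 3 for the unfolded protein response (0.15 against 0.12) and S phase (0.025 against 0.019). Nothing in these 5 lists passed singly over all genes tested or adjusted over the list alone.

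Lists tied to effector and resident T cells did not pass with camera. By fry's test for change in either direction 6 of the 30 lists passed, among them Notch targets (fry adjusted p = 4.38e-04), inhibitory receptors (0.00255), leukaemia transcription factors (0.00444) and cytotoxicity genes (0.00815). That test does not compare a list with other genes, and 2152 of the 16588 genes tested had an unadjusted limma p under 0.05. Passing it therefore does not set these lists apart from other genes. Of 12 tested cytotoxicity genes 9 were positive (camera adjusted p = 0.112; 0.0197 without ZNF683 library 1 and 0.0221 without Mock library 1). None passed over all genes and 2 were higher when adjusted over the list alone, 1 of them with median-of-ratios scaling. These were the perforin gene PRF1 (chromosome 10, 70597348 to 70602775), at 11.7 ± 2.34 against 5.99 ± 0.733 TPM (log2 change 0.85 ± 0.16, limma adjusted p = 0.222), and the cathepsin gene CTSW, at 30.6 ± 2.62 against 22.0 ± 2.72 TPM. Of 8 tested tissue residency genes, 4 were positive and 4 negative (camera adjusted p = 0.990), and 1 was higher when adjusted over the list alone, though not with median-of-ratios scaling: ITGA1, which encodes the CD49a integrin chain, at 8.58 ± 2.26 against 4.13 ± 1.12 TPM. CD69 had 41.7 ± 7.15 against 60.8 ± 17.4 TPM, and ITGAE, which encodes CD103, had 117 ± 21.7 against 122 ± 16.6 TPM. Memory and quiescence genes had 7 positive and 10 negative of 17 (camera adjusted p = 0.991), with LEF1 at 855 ± 155 against 624 ± 53.2 TPM and TCF7 at 102 ± 8.93 against 112 ± 7.05 TPM. Of 6 tested inhibitory receptor and exhaustion genes (camera adjusted p = 0.342), 2 were higher when adjusted over the list alone, TOX2 at 5.52 ± 0.278 against 3.44 ± 0.278 TPM and CD244 at 8.59 ± 0.912 against 5.54 ± 0.731 TPM.

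Leukaemia transcription factor genes went both ways (10 of 16 positive, camera adjusted p = 0.957). None passed over all genes. Among those lower when adjusted over the list alone, RUNX1 had 36.4 ± 1.78 against 50.2 ± 4.39 TPM and LMO1 had 8.39 ± 1.51 against 13.4 ± 2.37 TPM. TAL1, the factor misexpressed in this line, had 59.4 ± 7.19 against 45.2 ± 5.56 TPM. Among 9 Notch targets (camera adjusted p = 0.957), 2 were higher and 1 lower when adjusted over the list alone. DTX1 had 6.32 ± 0.761 against 3.78 ± 0.758 TPM, HES1 had 2.72, 4.13 and 4.12 against 1.80, 1.84 and 2.37 TPM, and PTCRA, which encodes the pre-T cell receptor alpha chain, had 6.06 ± 0.581 against 8.61 ± 1.27 TPM. The activation gene EGR1 had 3.11 ± 1.13 against 8.09 ± 3.57 TPM (log2 change -1.11 ± 0.32, limma adjusted p = 0.289).

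Among the doxycycline libraries, Dox- libraries 1 and 2 stood apart. AL135790.1 is annotated as a long intergenic RNA (chromosome 9, 10631750 to 10632203), though its longest transcript is 157 nt. It was chosen after its values were seen. It took 50.7% of all TPM in Dox- library 1, 12.8% in Dox- library 2 and 6.65% to 10.5% in the other 4 libraries. TPM is normalized by length, so these are not shares of reads. Protein-coding genes held 41.6% of TPM in Dox- library 1 and 74.9% in Dox- library 2, against 81.7% to 86.6% in the others. Dox- library 2 had the lowest correlations with the other libraries, 0.898 to 0.920, and 637 TPM of HSPA6, which was at most 0.351 TPM in the other 5. The median log2 change of all tested genes was 0.32 as deposited, so list changes are given relative to the other genes.

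**Figure D2:**
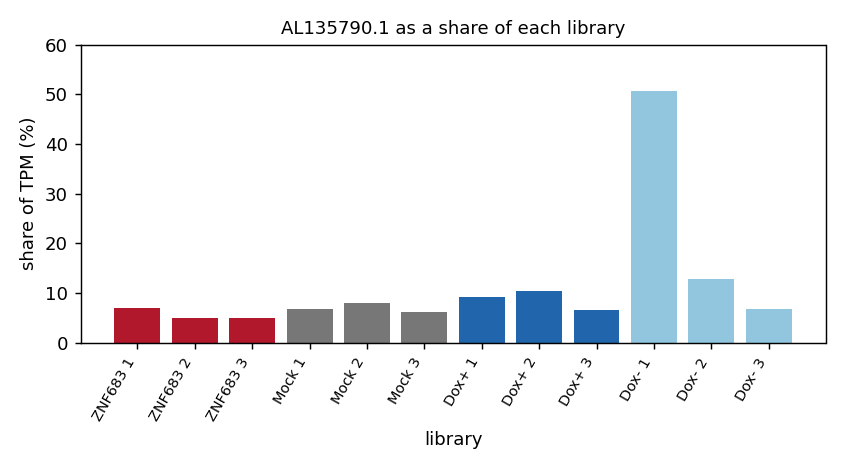
Share of all TPM taken by AL135790.1 in each of the 12 libraries (bars, percent, 1 library each), coloured by group. Dox- library 1 reached 50.7%, while the 6 libraries of the ZNF683 and Mock table lay between 4.94% and 7.96%.

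Against that background, 60 of 15148 tested genes passed the threshold with doxycycline, 19 higher and 41 lower. Of these, 13 were protein-coding and 23 had groups that did not overlap. Over all tested genes the groups of 8.80% did not overlap (11.7% with median-of-ratios scaling), against an average of 10% over the possible splits. By the naming rule PRF1 rose from 1.96 ± 1.57 to 6.91 ± 0.999 TPM (log2 change 1.54 ± 0.41, limma adjusted p = 0.0437), as did MIR647, BRCA1P1, CABCOCO1 and IGLV5-52. Among the falls, ADM, which encodes the hypoxia-inducible peptide adrenomedullin (chromosome 11, 10304680 to 10307397), went from 10.0 ± 11.4 to 0.757 ± 0.349 TPM (limma adjusted p = 1.12e-04), and AK4, a mitochondrial adenylate kinase gene (chromosome 1, 65147549 to 65232145), went from 19.0 ± 18.8 to 2.52 ± 0.588 TPM (limma adjusted p = 4.25e-04). The transcription factor gene KLF15 and RNU7-123P also fell. Called genes were often short: 55.8% of those with a known length were under 200 nt, against 3.74% of the genes tested. The limma count was 0 with median-of-ratios scaling (466 genes at an unadjusted p under 0.05), with AL135790.1 left out before rescaling (508) and without Dox- library 1 (446), 14 to 19 without a Dox+ library and 2788 without Dox- library 3. The balance of calls was not stable: 25 were higher and 15 lower without Dox- library 2, 2754 higher and 34 lower without Dox- library 3, and 29 higher and 29 lower with a pseudocount of 0.1. ADM, AK4 and PRF1 did not pass with median-of-ratios scaling or without Dox- library 1. With that scaling their log2 changes were -2.40, -2.42 and 1.27 (limma adjusted p = 0.752 for each), and their groups did not overlap. PRF1 and CABCOCO1 also missed the threshold with robust limma (adjusted p = 0.0521 and 0.129), and the groups of CABCOCO1 overlapped with median-of-ratios scaling.

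Of 29 lists tested, 14 passed at the preset correlation, 9 higher and 5 lower, and none with an estimated correlation (adjusted p = 0.935 with an estimated correlation for each) or by fry. Glycolysis and hypoxia genes were lower as a set with doxycycline (shift -0.73, camera adjusted p = 4.75e-16), with 24 of 30 members negative as deposited and 30 of 30 with median-of-ratios scaling. In that list ADM fell singly over all genes, and 2 members were lower when adjusted over the list alone, none with median-of-ratios scaling. The mitophagy receptor gene BNIP3 had 42.1 ± 6.39 against 108 ± 67.1 TPM. Integrated stress response genes were also lower (shift -0.62, camera adjusted p = 5.58e-10), with 16 of 24 negative, or 23 of 24 with median-of-ratios scaling. None of them passed singly over all genes. Adjusted over the list alone, none was lower as deposited and 5 were with median-of-ratios scaling, which lowers the doxycycline change of nearly every gene. In that list PPP1R15A, a phosphatase subunit gene, had 10.9, 13.1 and 12.9 TPM with doxycycline and 5.72, 334 and 12.9 TPM without, and DDIT3, which encodes CHOP, had 16.3 ± 2.55 against 68.6 ± 89.0 TPM, the highest library being Dox- library 2 in each case. Replication-dependent histone genes were lower (shift -0.51, camera adjusted p = 1.33e-05; 13 of 17 negative), but not without Dox- library 2 (camera adjusted p = 0.343). Heat shock genes (shift -0.37, camera adjusted p = 0.00225) and tissue residency genes (shift -0.43, camera adjusted p = 0.0129) had positive medians of 0.15 and 0.14 despite their lower shifts, and neither passed with median-of-ratios scaling (camera adjusted p = 0.212 and 0.635). HSPA1A and HSPA1B fell singly, from 12.5 ± 21.2 to 0.212 ± 0.134 and from 191 ± 322 to 6.74 ± 1.17 TPM, through Dox- library 2, and did not pass with robust limma (adjusted p = 0.751 and 0.783). Without that library the heat shock shift was 0.14 (camera adjusted p = 0.343).

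Genes of the T cell receptor complex and its proximal signalling were higher as a set with doxycycline (shift 0.49, camera adjusted p = 6.25e-07; 26 of 27 positive), none of them singly over all genes and 4 when adjusted over the list alone, none of these with median-of-ratios scaling. CD2, a costimulatory receptor gene, had 304 ± 25.6 against 136 ± 70.3 TPM and TRAT1 had 93.3 ± 12.7 against 42.1 ± 34.6 TPM. The CD2 groups did not overlap. Those of TRAT1 did as deposited, with Dox- library 3 at 80.3 TPM and Dox+ library 1 at 79.2 TPM, though not with median-of-ratios scaling. Cytotoxicity genes were higher (shift 0.33, camera adjusted p = 0.0152; 11 of 13 positive), PRF1 singly, but not without Dox- library 2 (camera adjusted p = 0.278). Actin cytoskeleton genes (shift 0.33, camera adjusted p = 8.44e-04), nuclear oxidative phosphorylation genes (0.24, camera adjusted p = 0.00896), interferon response genes (0.23, camera adjusted p = 0.0129) and MHC class I genes (0.25, camera adjusted p = 0.0402) were also higher as sets. As deposited, the list mean of Dox- library 3 lay within the Dox+ range for interferon response genes (0.48 against 0.46 to 0.52) and nuclear oxidative phosphorylation genes (0.52 against 0.44 to 0.62) and just under it for MHC class I genes (0.45 against 0.48 to 0.57), while Dox- libraries 1 and 2 lay at 0.14 or lower in all 3. With median-of-ratios scaling Dox- library 3 was under every Dox+ library for interferon response (0.11 against 0.16 to 0.19) and MHC class I genes (0.027 against 0.13 to 0.19), but not for oxidative phosphorylation genes (0.086 against 0.067 to 0.27). Mitochondrially encoded genes (0.32, camera adjusted p = 0.0173), mitochondrial ribosomal protein genes (0.23, camera adjusted p = 0.0173) and chemokine and trafficking receptor genes (0.29, camera adjusted p = 0.0488) passed as deposited but not with median-of-ratios scaling (camera adjusted p = 0.171, 0.0796 and 0.111). Cytosolic ribosomal protein genes did not pass as deposited (shift -0.05, camera adjusted p = 0.648) and were lower as a set with median-of-ratios scaling (shift -0.11, camera adjusted p = 6.44e-04). Without Dox- library 2, 4 lists passed, namely glycolysis and hypoxia, integrated stress response, T cell receptor and actin cytoskeleton genes.

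**Figure D3:**
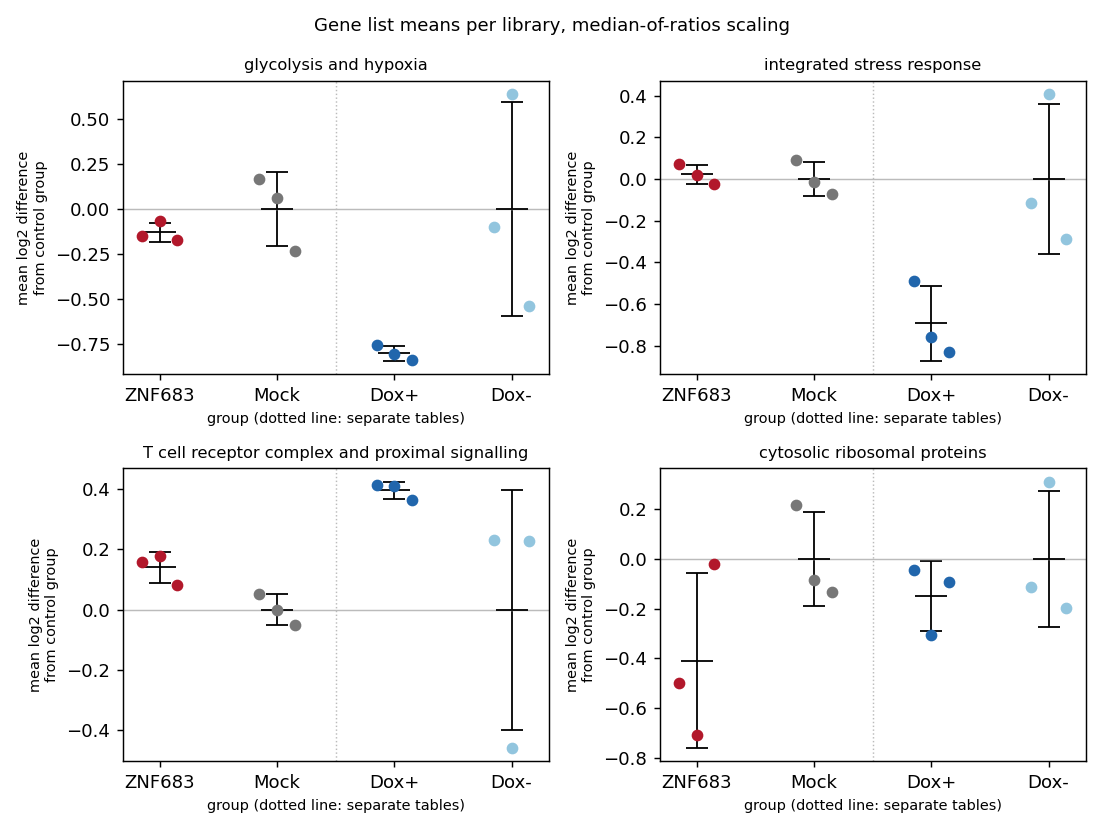
Mean log2(TPM + 1) difference of the glycolysis and hypoxia, integrated stress response, T cell receptor and cytosolic ribosomal protein lists from their control group (Mock or Dox-) per library after median-of-ratios scaling, each panel with its own axis; points are libraries, and the black bar and whiskers give the mean and SD of 3 libraries. The Dox+ libraries sat between -0.84 and -0.76 for glycolysis and hypoxia genes, while the Dox- libraries spread from -0.54 to 0.64.

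Of 14468 genes tested in both comparisons, 1 passed in the same direction in both, HSPA6, against 0.00166 expected from independent lists (two-sided Fisher exact p = 0.00166; genes are not independent replicates). In the doxycycline table HSPA6 passed through Dox- library 2 alone. Its groups overlapped, at 0.187, 0.183 and 0.351 TPM with doxycycline and 0.113, 637 and 0.341 TPM without, and with robust limma it did not pass (adjusted p = 0.753). The log2 changes of the 2 comparisons correlated across genes (Pearson r = 0.32, Spearman rho = 0.39; genes are not independent replicates). PRF1 had the same order in both tables but passed in the doxycycline table only, and its 2 changes were not shown to differ (limma adjusted p = 0.876). The limma test of the difference passed for 2 genes (543 at an unadjusted p under 0.05), both chosen after their values were seen. AC010619.2 had 18.2 ± 4.53 against 36.1 ± 6.12 TPM in the ZNF683 and Mock table and rose from 1.08 ± 0.622 to 18.7 ± 4.41 TPM with doxycycline. AC091117.1 had 3.04 ± 1.76 against 0.206 ± 0.357 TPM in the first and fell from 3.99 ± 0.912 to 0.341 ± 0.590 TPM in the second.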

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

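The tests of AL135790.1, of the doxycycline lists and of the ZNF683 level were chosen after those results were seen; the counts over other splits were planned. The criteria for absence of doxycycline and for the scaling of the doxycycline lists were also replaced after their values were known.

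The 2 comparisons differed by a test of the difference (first change minus second, log2) for AC091117.1 by 3.66 and for AC010619.2 by -4.23. At the preset correlation they also differed for 14 gene lists, and for none with an estimated correlation (adjusted p = 0.921 with an estimated correlation). The median differences, with those under median-of-ratios scaling in parentheses, were 0.17 (0.43) for tissue residency, -0.47 (-0.15) for leukaemia transcription factors, -0.63 (-0.29) for the T cell receptor complex, -0.51 (-0.22) for interferon response, -0.50 (-0.18) for MHC class I, 0.11 (0.37) for NF-kB targets, 0.33 (0.55) for histones and -0.015 (0.27) for ribosome biogenesis. They were -0.63 (-0.29) for cytosolic ribosomal proteins, 0.23 (0.57) for glycolysis and hypoxia, -0.63 (-0.30) for nuclear oxidative phosphorylation, 0.45 (0.72) for the integrated stress response, -0.039 (0.29) for heat shock and -0.51 (-0.18) for the actin cytoskeleton, the deposited values on a background in which the doxycycline changes had a median of 0.32. For ribosome biogenesis and heat shock the test was positive while the median as deposited was negative. Tissue residency, leukaemia transcription factors and heat shock did not pass with median-of-ratios scaling (camera adjusted p = 0.306, 0.144 and 0.0526). The unfolded protein response passed only with that scaling (camera adjusted p = 0.00656, against 0.0836 as deposited), with a median difference of 0.20.

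AL135790.1 made up 50.7% of TPM in Dox- library 1, and absence of doxycycline as the whole cause is argued against, since the higher of the other Dox- libraries had 0.251 times its level. A first criterion, that Dox- library 3 had 0.774 times the Dox+ mean, was given up because it rests on 1 library. Reads of low-complexity sequence are a candidate explanation: the transcript holds a run of 38 A or T bases, and of the genes at least 4 times as high there as the median of the other 5 libraries, leaving out 3 whose sequence had already been looked at, 41.3% held a long single-base run or 2-base repeat, against 14.1% of tested genes (two-sided Fisher exact p = 6.04e-06, genes not being independent replicates). That share depended on the definition, which was revised after results had been seen: over the 6 versions run it went from 26.4%, when genes at 0 in that library were counted and the test left the question undecided, to 88.9%, when the gene had to reach 4 times every other library, with shorter repeats and the genes already looked at counted (85.7% without those genes). What raised the values of such genes in 1 library was not tested.

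Glycolysis and hypoxia and integrated stress response genes were lower as sets with doxycycline at the preset correlation. Neither list passed with an estimated correlation (camera adjusted p = 0.935 for each) or by fry. A squeeze of all other values by AL135790.1 is argued against as the whole cause. It lowers values in Dox- library 1 and so works against a fall with doxycycline. With median-of-ratios scaling the member medians were -0.74 (upper quartile -0.47) and -0.71 (upper quartile -0.28), against -0.40 and -0.35 as deposited. That move was fixed by the scaling factors, 0.580, 0.999 and 1.20 for the Dox- libraries and 1.13 to 1.15 for the Dox+ libraries. They lower the doxycycline change of nearly every gene, so the move says nothing about these lists in particular. Whether Dox- libraries 1 and 2 alone carry the pattern stays open: Dox- library 3 lay above the highest Dox+ library by 0.22 and 0.20 on the log2 scale, which is 1 library. An effect of induced ZNF683 and an effect of doxycycline itself cannot be told apart. The Dox+ and Dox- libraries are of a line titled with the factor, with no Mock line given doxycycline beside them. ZNF683 was also not shown to be raised. The hypoxia list had a median change of -0.0075 between ZNF683 and Mock. That value does not separate the 2 effects either, since doxycycline in the Mock cells is not stated in the labels. Culture state, such as density or oxygen, was not recorded in the labels and not tested.

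ZNF683 was not past the threshold in the libraries labelled for it. An introduced sequence that the quantification did not count could leave the ZNF683 value flat, as would absence of induction, and the tables do not separate them: the lowest ZNF683 library had 0.651 times the highest Mock library, and no gene was named for an introduced sequence. A swap of labels between the groups is also open, with 0 libraries out of place beyond the whole other group but ranges that overlap.

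With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For ZNF683 against Mock, 1 of 10 splits gave at least the real 5 genes (highest other 3) and 9 of 10 at least the real 5 lists (highest other 14). For Dox+ against Dox-, 3 of 10 gave at least the real 60 genes (highest other 106) and 1 of 10 at least the real 14 lists (highest other 12). Over 100 regroupings within both tables, 4 gave at least the real 2 genes that differed (highest other 2), a share under 0.05. The 8 that gave at least the 1 gene shared in direction (highest other 1) do not exclude chance for that gene. Nor is chance excluded for the 2 differing genes. Other regroupings tied their count, the share was not adjusted for the other shares, and it was taken on deposited values, while median-of-ratios scaling left 1 gene.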

How the results depend on the processing

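Tests chosen only after seeing the data are protein-coding genes only, rescaling without AL135790.1 and leaving out Dox- libraries 1 and 2 together; depth could not be assessed from TPM, and the cause was not tested for any change below. Leaving out Dox- libraries 1 and 2 leaves 1 Dox- library, which is assumed to vary like the other groups (in the doxycycline table, like the Dox+ libraries), so values under it rest on that library and decide nothing about the group. The ZNF683 and Mock gene count of 5 became 3 with a pseudocount of 0.1, 0 with a pseudocount of 5, 0 with no filter, 0 with a minimum of 5 TPM, 8 with robust limma, 19 with library quality weights (8 higher, 11 lower, against 3 and 2), 1 with protein-coding genes and 1 with those and median-of-ratios scaling. Its list count of 5 (4 higher, 1 lower) became 10 with no filter and 0 with an estimated correlation or fry's directional test, with 6 by fry in either direction; 3 lists were higher and 2 lower with quantile normalization, and 3 higher and 3 lower with a minimum of 5 TPM or protein-coding genes, with or without median-of-ratios scaling. The doxycycline gene count of 60 (19 higher, 41 lower) had 29 higher and 29 lower with a pseudocount of 0.1 and 8 higher and 51 lower with a pseudocount of 5. It became 0 with no filter, 15 with a minimum of 5 TPM, 0 with median-of-ratios scaling, quantile normalization, rescaling without AL135790.1, protein-coding genes with median-of-ratios scaling, or Dox- libraries 1 and 2 left out, 23 with robust limma (9 higher, 14 lower), 2 with quality weights and 9 with protein-coding genes (1 higher, 8 lower). Its list count of 14 (9 higher, 5 lower) became 8 with a minimum of 5 TPM (3 higher, 5 lower), 9 with quantile normalization, 9 without Dox- libraries 1 and 2, and 0 with an estimated correlation or either fry test; it had 15 higher and 3 lower with no filter and 5 higher and 5 lower with protein-coding genes and median-of-ratios scaling. The 2 genes differing between comparisons became 1 with median-of-ratios scaling, quantile normalization, rescaling without AL135790.1 or Dox- libraries 1 and 2 left out, and 0 with quality weights, protein-coding genes or those with median-of-ratios scaling. The 1 gene shared in direction became 0 with a pseudocount of 5, no filter, a minimum of 5 TPM, median-of-ratios scaling, quantile normalization, robust limma, quality weights, rescaling without AL135790.1, protein-coding genes with median-of-ratios scaling, or Dox- libraries 1 and 2 left out.

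Leaving out 1 library gave 0 to 49 genes and 5 to 8 lists for ZNF683 against Mock, 0 to 2788 genes and 4 to 14 lists for Dox+ against Dox-, 1 to 2550 genes differing and 0 to 1 shared. The extremes were 49 genes without ZNF683 library 1, 3 without ZNF683 library 2, 1 without Mock library 1, 0 without Mock library 2 and 8 without Mock library 3; 0 without Dox- library 1, 14 to 19 without a Dox+ library and 2788 without Dox- library 3; and, for genes differing, 1 without ZNF683 library 1 or Dox- library 1, 5 without Mock library 3, 25 without Dox- library 2 and 2550 without Dox- library 3. Higher and lower calls were 42 and 7 without ZNF683 library 1, 25 and 15 without Dox- library 2 and 2754 and 34 without Dox- library 3, and lists 5 and 6 without Dox- library 1. The shared gene was lost without ZNF683 library 2 or 3, Mock library 1 or 2 or any Dox- library. Of results past the threshold in the main test or the alternative, directions reversed for heat shock in the doxycycline table with no filter (-0.18, test of the opposite sign, adjusted p = 0.890) and without Dox- library 2 (0.14, in a leave-one-out range from -0.72), for HSPA1B without Dox- library 2 (0.46, in a range from -3.12), and, with Dox- library 3 as the only Dox- library, for tissue residency (0.17) and mitochondrial ribosomal proteins (-0.12); chemokine and trafficking receptors there had a shift of -0.0031 and did not pass. Counted over all named results, signs differed from the main value 6 times in 5 genes and 4 times in 4 lists for doxycycline, and 3 times in 2 genes and 25 times in 4 lists for ZNF683 against Mock. Those 4 lists were memory and quiescence, tissue residency, T cell activation and leukaemia transcription factors, and the 2 genes AL135790.1 and ITGAE, none past the threshold in either setting. Over named genes, 189 of 785 alternative values in the doxycycline comparison lost a call and 14 gained one. For ZNF683 against Mock 30 of 850 lost a call.

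Shared replicate numbers were not shown to pair the samples, and pairing was not excluded. Correlations of same-numbered deviations were -0.21, 0.068 and -0.25 for ZNF683 and Mock and 0.076, 0.055 and 0.36 for doxycycline. ZNF683 library 2 and Dox+ libraries 2 and 3 correlated best with the control library of their own number, and the others did not. In the doxycycline titles each number occurs with and without the drug, so the main test may ignore a pairing there. With the replicate number as a block, 0 genes passed for ZNF683 against Mock and 34 for doxycycline, with 7 and 16 lists, 60 genes differed between comparisons, and 0 were shared in direction.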

Other observations

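The correlation test below was planned before its result was seen. In the ZNF683 and Mock table, 17.2% of tested genes had groups that did not overlap (19.5% with median-of-ratios scaling), and for doxycycline the share was 8.80% (11.7% with that scaling). The average over the possible splits is 10%. The share was computed for the real split only and genes are not independent, so its distance from 10% was not tested. Other lists that did not pass for ZNF683 against Mock included G2/M phase (30 of 51 positive, camera adjusted p = 0.957), interferon response (16 of 34 positive, camera adjusted p = 0.957) and nuclear oxidative phosphorylation (14 of 42 positive, camera adjusted p = 0.0772).

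A hypothesis that both comparisons share an effect was tested by regrouping the libraries within both tables. The real Spearman rho with median-of-ratios scaling was 0.36, and 9 of 100 regroupings, the real one included, lay as far from 0, with the highest other at 0.48. As deposited the counts were 8 for Spearman and 10 for Pearson. Chance sharing is therefore not excluded, and the correlation across genes may come from structure among the libraries.

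Dox- library 2 had 317 genes at least 4 times as high as in every other library of its table, against 2 to 9 in the other 5 libraries. HBA2, an alpha globin gene, was at 14.8 TPM in it and at or under 0.444 TPM in the others.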
